A study of Homo sapiens with 6 samples.

How the data were processed

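RNA from LNCaP prostate cancer cells was measured on Affymetrix arrays with 22283 probe sets, 1 array per culture, 48 hours after transfection. The 3 groups of 2 arrays were control, HOXC6 siRNA (5 siRNAs together, 100 nM) and HOXC6 overexpression (4 µg of vector), as the sample titles and descriptions give them. The titles call the arrays of a group biological replicates. The series description gives control siRNA and vector for the control cultures; whether each of them received 1 or both is not given in the sources used here.

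The values deposited by the authors are signal intensities per probe set on a linear scale, made with MAS5, whose version is not given in the sources used here. On every array the mean without the top and bottom 2% of probe sets was close to 150.1, so each array carries 1 scaling factor and no further normalization was seen. Detection calls were not used here. The number of arrays limits the precision. No coordinates were used, since no genome build is given for the array; the reference annotation served only for gene names.

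Of the probe sets, 68 are controls, 19071 carry 1 gene symbol, 1043 several and 2169 none. Probe sets with 1 symbol covered 11963 genes, and each gene was represented by the probe set with the highest mean over the 6 arrays; 4310 genes had more than 1. Genes whose mean signal reached the 40th percentile of probe sets (51.5) were tested, 8230 in all. The symbols were checked against the reference table through the gene identifiers, of which 19059 matched, and 0 symbols changed.

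Group differences were estimated on log2(signal + 16) with limma 3.58.1 in R 4.3.3, by lmFit and eBayes without an intensity trend, in 1 fit over all 6 arrays with 3 residual and 3.987 prior degrees of freedom. The 3 comparisons were siRNA with control, overexpression with control and overexpression with siRNA, all two-sided. P values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. HOXC6 was reported in every array whether or not it passed, and its 3 tests were also adjusted among themselves. Fold values are powers of 2 of the log2 change, so they refer to signal + 16. Simulated data were made by adding known 2-fold changes to 100 genes and 4-fold changes to 100 others. Fits recovered 70% to 73% of 4-fold changes and 2% to 4% of 2-fold changes, with 2 to 8 false calls. The simulated noise was independent between genes and of the same spread in all groups, unlike these arrays, so these shares may not hold here. HOXC6 itself, 4.44-fold lower with siRNA, did not pass over all genes.

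Before the data were examined, 31 gene lists were fixed: genes reported in earlier work as HOXC6-regulated, HOX genes with PBX and MEIS partners, androgen-induced and androgen-repressed genes, markers of luminal, basal, neuroendocrine, stromal and leukocyte cells, G1/S and G2/M cell cycle, p53 targets, pro-apoptotic and anti-apoptotic genes, the interferon, NF-kB and immediate early responses, the unfolded protein and integrated stress response, heat shock, cholesterol and fatty acid synthesis, hypoxia and glycolysis, cytosolic ribosomal proteins, oxidative phosphorylation, the proteasome, BMP and TGF-beta, FGF, PDGF and IGF, Wnt and Notch signalling, mesenchymal and adhesion genes, and the RNA interference machinery. The 30 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, and adjusted over 90 tests. The list of reported HOXC6-regulated genes had 4 tested members, so its genes were tested singly. Members were counted both over all genes tested and adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were the alternatives; no list passed with either. Lists share members, such as BNIP3 and IGFBP3.

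Genes named in the text were chosen by a rule fixed in advance. For each comparison it takes HOXC6, up to 12 higher and 12 lower genes with the largest change among those past the threshold whose arrays do not overlap, or, where fewer pass, up to 8 per direction by the smallest p, given as values. It adds up to 4 members per described list by smallest p, every member of the first list, and up to 6 genes per direction that moved oppositely or alike with siRNA and overexpression at an unadjusted p under 0.05. Genes named outside this rule are HOXB13, GAPDH and ACTB in the comparisons, and those of the closing observations; they were chosen after their values were seen.

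The correlation of the siRNA and overexpression changes was taken over the genes tested, with 100 simulations of the value, and of the counts of genes with alike or opposite signs, that the shared control arrays alone would give. Array quality was described by 18 spike-in probe sets, 27 probe sets for bacterial transcripts that are not spiked, 9 ribosomal RNA probe sets, and the 3' minus 5' differences of ACTB and GAPDH. The median of the probe sets that are not spiked, per group, served as background for named genes, a step chosen after the data were seen.

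Alternatives fixed in advance were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median centring, replicate number as a block, fits of only the 2 groups compared, an intensity trend, the mean over a gene's probe sets, leaving out each array, and a minimum of 2-fold. Cyclic loess, array weights, a block with the overexpression numbers exchanged, and the rank of each list among 10000 random lists of like signal were added after the data were seen. The random lists draw genes independently, so the ranks leave out correlation within a list. A group left with 1 array was assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.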

Results

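Messenger RNA levels were measured on Affymetrix arrays in LNCaP cells, an androgen-responsive human prostate cancer line, after the level of the homeobox transcription factor HOXC6 had been lowered or raised. Total RNA was taken 48 hours after transfection. There were 3 groups of 2 arrays each: control transfections, cells given 5 HOXC6 siRNAs together at 100 nM, and cells given 4 µg of a HOXC6 expression vector. The titles call the arrays of a group biological replicates. All 6 arrays were used, and their small number limits the precision of every value. Values are array signals, and changes are differences of log2(signal + 16) between group means, given with the standard error of the limma fit (n = 2 per group). An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333, so none was used.

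Both transfections moved HOXC6 itself. Its signal was 447.1 and 528.7 in the control arrays (mean 487.9 ± 57.7, SD, n = 2), 102.9 and 91.8 in the siRNA arrays (mean 97.4 ± 7.85), and 69552 and 37626 in the overexpression arrays (mean 53589 ± 22575). With siRNA the log2 change was -2.15 ± 0.36, a 4.44-fold drop, and HOXC6 ranked 1 of 8230 genes by limma's p. Adjusted over the 3 HOXC6 comparisons its p was 0.000608, but adjusted over all 8230 genes it was 0.999. With the vector HOXC6 rose by 6.67 ± 0.36 on the log2 scale, 102-fold, with a limma adjusted p of 0.00304 over all genes. Without control replicate 1 that adjusted p was 0.0571, at a log2 change of 6.55, and over all alternatives it ran from 3.78e-06 to 0.0571. Between overexpression and siRNA the difference was 8.82, or 452-fold (limma adjusted p = 0.000443).

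**Figure D1:**
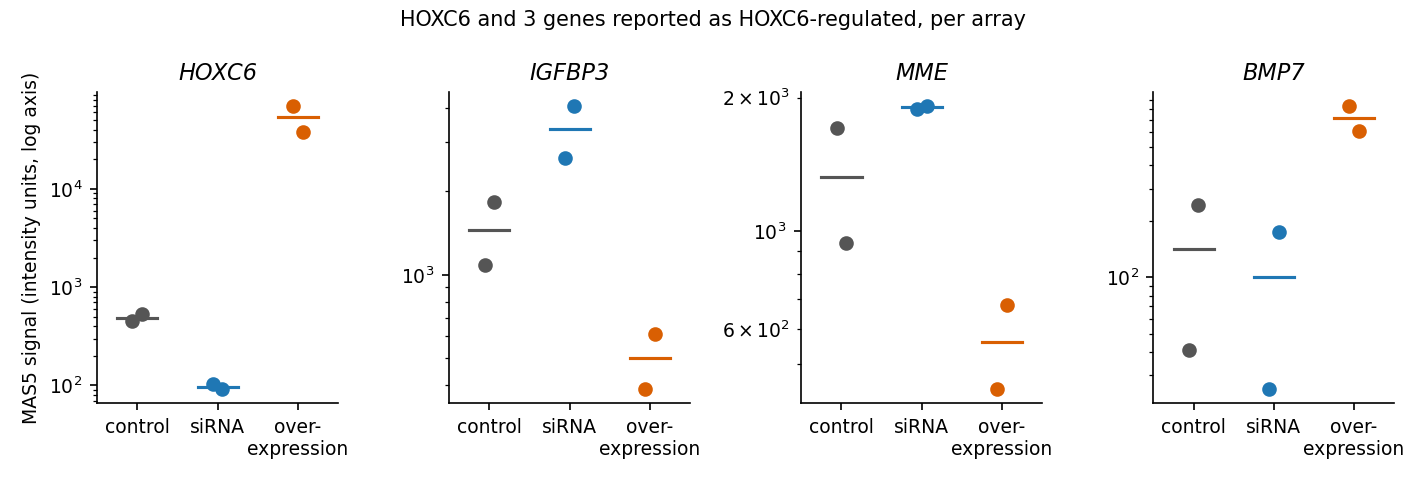
Array signal (log axis) of HOXC6, IGFBP3, MME and BMP7 in each of the 6 arrays, by group; each point is 1 array and the line is the group mean. HOXC6 lies near 97.4 in the siRNA arrays, 487.9 in the controls and 53589 with the vector, and IGFBP3 runs the other way, from a mean of 3349 with siRNA through 1452 in the controls to 499 with overexpression.

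The overexpression arrays stood apart from the other 4 in measures that do not involve HOXC6. Spike-in transcripts read 3.33 and 2.33 times the control mean on them. The log2 signal of the 3' minus the 5' probe set of ACTB (beta-actin) was 1.14 ± 0.15 (SD, n = 2), against 0.37 ± 0.12 in the controls and 0.55 ± 0.37 with siRNA. For GAPDH, a glycolytic enzyme, the corresponding values were 0.30 ± 0.03, -0.33 ± 0.04 and -0.12 ± 0.44. The 90th percentile of signal was 24.8 and 35.2 times the 10th on the overexpression arrays, 73.8 and 53.1 times on the control arrays, and 71.6 and 50.3 times on the siRNA arrays. Across genes, which are not independent replicates, the overexpression pair correlated with r = 0.791, the control pair with 0.929 and the siRNA pair with 0.935. Overexpression replicate 2 had r from 0.810 to 0.828 with the control and siRNA arrays, above its r with overexpression replicate 1. Overexpression replicate 1 had 0.655 to 0.694 with the control and siRNA arrays, so the 2 overexpression arrays were not alike.

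**Figure D2:**
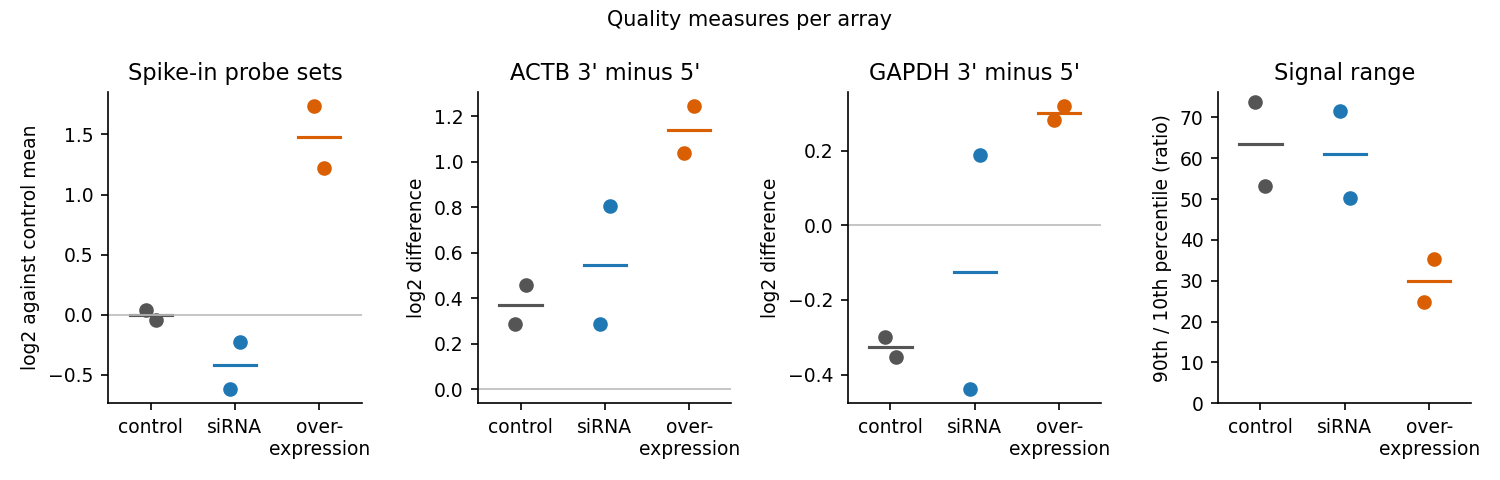
Measures of array quality in each of the 6 arrays, by group: spike-in signal and the 3' minus 5' differences of ACTB and GAPDH on the log2 scale, and the ratio of the 90th to the 10th percentile of signal. Both overexpression arrays lie above the others in the spike-in panel (3.33 and 2.33 times the control mean) and below them in the ratio (24.8 and 35.2).

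The comparison of HOXC6 siRNA with control asks which genes follow the loss of HOXC6. Genes that androgens induce were lower as a group in the siRNA arrays: 22 of the 30 measured lay below control, with a median log2 change of -0.30 (camera adjusted p = 0.000354; adjusted p = 0.846 with an estimated correlation). KLK3, which encodes prostate-specific antigen, had a signal of 6833 ± 2667 (SD, n = 2) in the controls and 3559 ± 1826 with siRNA, a log2 change of -0.98 ± 0.45. Androgen-repressed genes were higher as a group: 5 of 6 lay above control, with a median of 0.63 (adjusted p = 0.00893; adjusted p = 0.846 with an estimated correlation). Genes of the G2/M phase of the cell cycle were lower, 26 of 30 below control with a median of -0.31 (adjusted p = 0.000709; adjusted p = 0.846 with an estimated correlation). No single gene passed over all genes with siRNA, so the changes of members that follow are values, not calls.

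Among the androgen-induced genes, HPGD (a prostaglandin-degrading dehydrogenase) had a log2 change of -0.99 ± 0.33, ELL2 (an elongation factor subunit) of -0.88 ± 0.38 and ZBTB10 (a zinc finger protein) of -0.66 ± 0.28. In the androgen-repressed list, DDC, which encodes an amine-forming decarboxylase, had 1.23 ± 0.80, CAMK2N1 (an inhibitor of the kinase CaMKII) 0.87 ± 0.28, the chemokine receptor ACKR3 0.69 ± 0.41 and FOLH1 (prostate-specific membrane antigen) 0.57 ± 0.31. Of the G2/M list, the mitotic kinase CDK1 had -0.91 ± 0.47, the checkpoint kinase BUB1B -0.65 ± 0.27 and survivin (BIRC5) -0.54 ± 0.28, whereas CKS2 (a CDK-binding protein) had 0.57 ± 0.28. The other probe set of ELL2 had 0.53, those of HPGD, whose signal with siRNA (6.20) was below background, lay between -0.49 and 0.23, and those of BIRC5 had 0.14 and -0.32. The lists of G1/S genes (24 of 28 lower, median -0.27, adjusted p = 0.0274), of hypoxia and glycolysis genes (17 of 21 lower, -0.22, 0.0419) and of proteasome subunits (23 of 27 lower, -0.12, 0.0498) also passed camera as lower, and cytosolic ribosomal proteins passed as higher (40 of 50, 0.12, 0.0333). With an estimated correlation the G1/S list had an adjusted p = 0.851, hypoxia and the proteasome an adjusted p = 0.846, and the ribosomal proteins an adjusted p = 0.891. In limma's test 0 members of these 7 lists passed over all genes and 0 adjusted over the list alone, and 4 (HPGD, ZBTB10, CAMK2N1 and the mitophagy receptor BNIP3, at -0.74) had an unadjusted p under 0.05. The androgen-induced call ended without control replicate 1 (adjusted p = 0.465) and without siRNA replicate 2 (0.121), and so did those of G2/M (0.653 and 0.660) and G1/S (0.710, with camera's direction turned, and 0.941), while the androgen-repressed call ended without control replicate 2 (0.148), without siRNA replicate 1 (0.225) and after quantile normalization (0.0586). The G1/S call also ended after quantile normalization and cyclic loess. Of 19 alternatives, the call of hypoxia and glycolysis ended in 12, that of the proteasome in 11 and that of ribosomal proteins in 7. Without control replicate 1 the medians were -0.17 for androgen-induced, -0.12 for G2/M, -0.04 for G1/S and -0.03 for hypoxia and glycolysis genes. Without control replicate 2 they were -0.57, -0.57 and -0.53 for androgen-induced, G2/M and G1/S genes, and without siRNA replicate 1 -0.46, -0.55 and -0.46. Without siRNA replicate 2 they were -0.19, -0.10 and -0.05, with -0.06 for the proteasome and 0.21 for ribosomal proteins. Among 10000 random lists of like signal, the median of the androgen-induced list stood at the percentile 0, G2/M at 0, G1/S at 0.01, hypoxia and glycolysis at 0.12, the proteasome at 2.05, ribosomal proteins at 98.8 and androgen-repressed genes at 99.98. These ranks leave out the correlation within a list, estimated at 0.11 for androgen-induced, 0.25 for G2/M and 0.27 for G1/S genes. Control replicate 1 alone lay above control replicate 2 for 27 of 30 G2/M and 23 of 28 G1/S members. Extreme ranks can therefore arise from a difference between single arrays. Over all alternatives the adjusted p ran from 1.68e-07 to 0.465 for androgen-induced, 1.68e-07 to 0.660 for G2/M, 3.65e-06 to 0.941 for G1/S and 0.00112 to 0.225 for androgen-repressed genes. The 3' minus 5' difference of ACTB was 0.81 in siRNA replicate 2, against 0.29 in siRNA replicate 1 and 0.29 and 0.46 in the controls.

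Of the 5 genes reported in earlier work as regulated by HOXC6, 4 were bright enough to test. That earlier work may rest in part on these same transfections, so the list is not independent evidence. IGFBP3, which binds insulin-like growth factors, had a signal of 1452 ± 525 (SD, n = 2) in the controls and 3349 ± 995 with siRNA, a log2 change of 1.21 ± 0.41 (limma adjusted p = 0.0839 adjusted over the list alone). MME (neprilysin, a membrane peptidase) had 0.58 ± 0.39 (0.358 over the list alone), with 0.15 without control replicate 2 and 1.01 without control replicate 1. BMP7, a bone morphogenetic protein, had -0.45 ± 0.88 and the growth factor receptor FGFR2 -0.13 ± 0.57 (both 0.825). The signs of these last values were not stable, BMP7 standing at 0.64 without control replicate 2 and at 0.65 without siRNA replicate 1, and FGFR2 at 0.21 and 0.02. PDGFRA, a platelet-derived growth factor receptor, was not tested, with mean signals of 5.50 in the controls, 6.15 with siRNA and 61.8 with overexpression.

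In limma's test of all genes 0 of 8230 passed with siRNA, and 221 had an unadjusted p under 0.05 (111 higher, 110 lower) where chance alone gives 411.5. That fit shares its spread with the more variable overexpression arrays. The number was 394 with only the 2 groups in the fit and 412 with array weights. The 2 siRNA arrays did not overlap the 2 control arrays for 32.5% of genes, against 33.3% by chance. The smallest p of the higher genes belonged to SLC43A3 (an amino acid and purine transporter family member), with a log2 change of 1.58 ± 0.29. GBP1, an interferon-induced GTPase, had 1.95 ± 0.36 and was the only member of the interferon list past the threshold when adjusted over the list alone (limma adjusted p = 0.0324). By p, next came DAZAP2 (1.56 ± 0.31), the beta-defensin DEFB1 (1.41 ± 0.35), SAYSD1 (1.27 ± 0.32), the AP-1 subunit JUND (1.49 ± 0.38), HNRNPM, an RNA-binding splicing regulator (1.96 ± 0.50), and choline kinase CHKB (1.26 ± 0.32). The control signals of SLC43A3 and GBP1 (11.2 each) and DEFB1 (11.95) lay below the median of bacterial probe sets that are not spiked (13.15), as did that of L1TD1 with siRNA (11.2 against 14.85), so the sizes of these 4 changes are not exact. On the lower side stood MBTPS2, a protease that activates SREBP (-1.72 ± 0.31), pantothenate kinase PANK3 (-1.66 ± 0.33), L1TD1 (-1.87 ± 0.38), the long noncoding RNA TUG1 (-1.40 ± 0.29), NIPA2 (-1.61 ± 0.34), the DNA repair glycosylase TDG (-1.39 ± 0.31) and TMF1 (-1.19 ± 0.27). The other probe sets of TMF1 had 0.11 and 0.68, and that of SLC43A3 -0.18. Camera passed none of the other 23 lists with siRNA, whose medians ran from -0.27 to 0.16 and whose adjusted p from 0.131 to 0.9997. Median, mean and camera's direction differed in sign there for luminal, stromal, immediate early, cholesterol synthesis, BMP and TGF-beta, and mesenchymal genes.

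The comparison of HOXC6 overexpression with control asks which genes follow a gain of HOXC6. Besides HOXC6, genes that rose included GRIN1, an NMDA receptor subunit (4.16 ± 0.38 on the log2 scale), and ACAP1, a GTPase-activating protein of membrane traffic (3.76 ± 0.45), although the other probe sets of GRIN1 lay between -0.87 and 2.24 and that of ACAP1 at 0.54. The folate receptor FOLR2 rose by 3.40 ± 0.32. The control signals of GRIN1 (13.6) and FOLR2 (10.3) lay near 13.15, the median of bacterial probe sets that are not spiked, so the size of these changes is not an exact fold; 24 of the 167 genes called higher lay below that median in the controls. Genes of the HOX family and their PBX and MEIS partners were higher as a group, 11 of 13 above control with a median of 0.95 (camera adjusted p = 0.0225; adjusted p = 0.846 with an estimated correlation). The call ended without control replicate 1 (median 0.40, adjusted p = 0.0715), without overexpression replicate 1 (0.80, 0.163) and with a filter at the 60th percentile (0.167), within a range over alternatives of 0.00693 to 0.240. HOXB1 (2.45 ± 0.29, limma adjusted p = 0.0311) and HOXD9 (2.04 ± 0.37, 0.0439) passed over all genes, and 5 members passed when adjusted over the list alone, HOXB7 (1.87 ± 0.47) and HOXC13 (1.39 ± 0.39) among them. The change of HOXC13 was no larger than the largest rise of a bacterial probe set that is not spiked (1.57). Among genes that fell were POR, the electron donor of cytochrome P450 enzymes (-2.34 ± 0.30), and the epithelial transcription factor EHF (-2.24 ± 0.37). The signal of POR with overexpression (16.45) lay below 35.45, the median there of bacterial probe sets that are not spiked, so the size of its fall is not exact.

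IGFBP3 and MME, which had been above control with siRNA, lay below it with overexpression, and BMP7 above it. The log2 changes were -1.50 ± 0.41 for IGFBP3, -1.19 ± 0.39 for MME and 2.58 ± 0.88 for BMP7. Adjusted over the list alone, which is not independent evidence, each had a limma adjusted p of 0.0297; over all genes these were 0.0866, 0.125 and 0.136. The other probe set of IGFBP3 had -0.51, that of MME -1.40, and the 3 others of BMP7 lay between 0.66 and 1.71. FGFR2 had 1.03 ± 0.57 (0.112 over the list alone). Without control replicate 1, BMP7 had 1.49 and MME -0.76; FGFR2 had 0.17 without overexpression replicate 1 and 1.89 without overexpression replicate 2. Over the list alone, all 3 calls ended without overexpression replicate 1 (limma adjusted p = 0.118 each) and after cyclic loess, with 0.0729 for IGFBP3 and BMP7 and 0.0850 for MME, whose value there was -0.75. Over left-out arrays these adjusted p ran from 0.0148 to 0.118 for IGFBP3, 0.0172 to 0.180 for MME and 0.0184 to 0.180 for BMP7. The calls of BMP7 and MME ended also without control replicate 1 (0.180), that of IGFBP3 without control replicate 2 (0.0802), that of BMP7 without overexpression replicate 2 (0.0532) and that of MME after quantile normalization (0.0552).

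Genes of FGF, PDGF and IGF signalling were higher as a group, 17 of 20 above control with a median of 0.77 (camera adjusted p = 0.0140; adjusted p = 0.846 with an estimated correlation). In limma's test 0 passed over all genes (7 higher and 1 lower at an unadjusted p under 0.05), while 4 were higher and 1 lower when adjusted over the list alone. The higher ones were the transcription factor ETV5 (1.69 ± 0.33), FGFR3 (1.46 ± 0.32), IGF1 (2.08 ± 0.46) and the insulin receptor INSR (1.86 ± 0.50), and the lower one was IGFBP3. The other probe set of FGFR3 had -0.00 and that of INSR -0.84, and those of IGF1 lay between -0.12 and 0.54.

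In the values as deposited, groups of abundant housekeeping transcripts were lower. Oxidative phosphorylation had 45 of 55 members below control (median -0.42, adjusted p = 0.000228), the proteasome 24 of 27 (-0.45, 0.00124) and cytosolic ribosomal proteins 41 of 50 (-0.28, 0.00387). With an estimated correlation the first 2 had an adjusted p = 0.846 and the ribosomal proteins an adjusted p = 0.851. Heat shock genes had 13 of 14 below control (-0.57, 0.00893), fatty acid synthesis 10 of 12 (-0.65, 0.0140), androgen-induced genes 25 of 30 (-0.40, 0.0140) and hypoxia and glycolysis 16 of 21 (-0.42, 0.0225). With an estimated correlation these 4 had an adjusted p = 0.846. Over all genes, the ribosomal proteins RPL23A (-1.75 ± 0.29) and RPS3 (-1.59 ± 0.28), the respiratory complex I subunit NDUFC1 (-1.58 ± 0.28) and the androgen-induced ZBTB10 (-1.51 ± 0.28) fell, and adjusted over the list alone these were again 2, 1 and 1 lower members. Adjusted over the list alone, STIP1 (-1.37 ± 0.35), FKBP4 (-1.19 ± 0.31) and CHORDC1 (-1.09 ± 0.29), all cochaperones, were also lower, and the androgen-induced HPGD was higher (1.64 ± 0.33), against its list. The other probe set of STIP1 had -0.18 and that of FKBP4 -0.07. In the proteasome, fatty acid and hypoxia lists 0 members passed limma's test over all genes or adjusted over the list alone, with 5, 6 and 5 at an unadjusted p under 0.05. The androgen-regulated protease TMPRSS2 had -1.63 ± 0.47 and FKBP5, whose signal of 26.8 with overexpression was below background, -1.40 ± 0.43, the fatty acid enzymes TECR -1.96 ± 0.54 and ACSL1 -0.95 ± 0.30, the mitophagy receptor BNIP3 -1.18 ± 0.29 and the proteasome subunit PSMA5 -1.24 ± 0.27.

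The signal range of the overexpression arrays was narrower, as given above, and change varied with signal. The median log2 change was 0.47 in genes with a mean signal of 50 to 100 and -0.47 in genes above 1600, and spike-in signal was 2.78 times the control mean. All 9 list calls of this comparison ended after quantile normalization and after cyclic loess, where the ribosomal median turned to 0.04 and 0.20. After cyclic loess the lists of oxidative phosphorylation and the proteasome had medians of -0.01 and -0.03, fatty acid synthesis had -0.37, heat shock -0.27, androgen-induced genes -0.11 and hypoxia and glycolysis -0.09, while FGF, PDGF and IGF signalling had 0.57 and HOX genes had a median of 1.00 (adjusted p = 0.240, within a range over alternatives of 0.00693 to 0.240). Among 10000 random lists of like signal, the median of oxidative phosphorylation stood at the percentile 41.2, the proteasome at 32.4, hypoxia and glycolysis at 13.7, androgen-induced genes at 6.98, heat shock at 4.17, fatty acid synthesis at 1.19, HOX genes at 98.7, FGF, PDGF and IGF signalling at 99.1 and ribosomal proteins at 99.9. Oxidative phosphorylation, the proteasome and ribosomal proteins were thus not low for their signal. Without control replicate 1 there were 4 lists past the threshold and without overexpression replicate 1 there were 3. The calls of androgen-induced, heat shock, fatty acid, and hypoxia and glycolysis genes ended in both cases, as the HOX call did, and that of ribosomal proteins without overexpression replicate 1; that of FGF, PDGF and IGF signalling ended with a filter at the 60th percentile (median 0.49). Without control replicate 1 the medians were -0.20 for androgen-induced and -0.27 for hypoxia and glycolysis genes. Without overexpression replicate 1 they were -0.20 for hypoxia and glycolysis, -0.34 for heat shock, -0.11 for ribosomal proteins and -0.25 for oxidative phosphorylation.

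**Figure D3:**
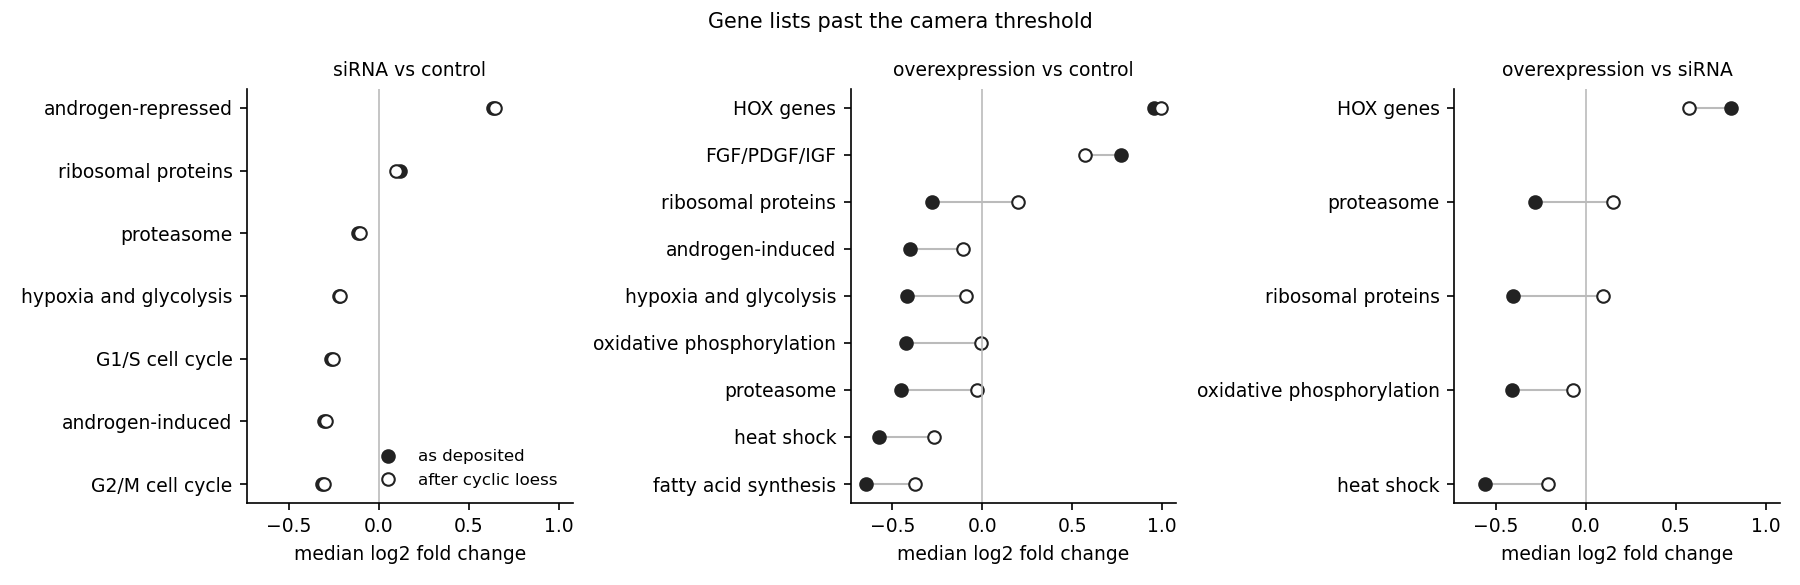
Median log2 change of the tested members of each gene list that passed camera, in 1 panel per comparison; filled points are values as deposited and open points values after cyclic loess. The ribosomal list with overexpression against control moves from -0.28 to 0.20, and the androgen-induced list with siRNA from -0.30 to -0.29.

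In limma's test 230 of 8230 genes passed with overexpression against control, 167 higher and 63 lower (72.6% higher), and 2091 had an unadjusted p under 0.05. The count depended on which array was left out: it was 0 without control replicate 1 (1137 at an unadjusted p under 0.05), 1 without control replicate 2, without either siRNA array or without overexpression replicate 1, and 1242 without overexpression replicate 2. It also depended on the settings, with 6 at a pseudocount of 1 and 626 at 64, 43 without a filter, 152 after quantile normalization, 1 with only the 2 groups in the fit, 7 with array weights and 481 with an intensity trend. The arrays of the 2 groups did not overlap for 56.7% of genes, against 33.3% by chance. The split of directions depended on scaling: 46.1% of the calls were higher after quantile normalization, 53.1% after cyclic loess and 36.0% after median centring, which moved the median of all genes to -0.36. The called higher genes were dim in the controls, with a median signal of 28.7 that became 208 with overexpression; the called lower ones went from 168 to 36.1, and 30 of these 63 ended below the median of bacterial probe sets that are not spiked (35.45). Further genes that rose were MAP2K5, a kinase of the ERK5 pathway (4.07 ± 0.29), RAB2A, a small GTPase of membrane traffic (3.69 ± 0.43), the salivary proline-rich protein PRB3 (3.31 ± 0.30), the calcium pump ATP2A3 (3.30 ± 0.64), ASIC4 (3.21 ± 0.45), the chromatin reader L3MBTL1 (3.11 ± 0.49) and REEP2 (3.05 ± 0.53). A probe set annotated to the read-through transcript SEPT5-GP1BB had 3.44 ± 0.47. The control signals of PRB3 (8.80), ATP2A3 (10.4) and SEPT5-GP1BB (12.45) lay below the median of bacterial probe sets that are not spiked (13.15), so the sizes of these changes are not exact. The other 5 probe sets of RAB2A lay between -0.77 and -0.07, and those of MAP2K5 between -0.54 and 0.43.

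Further genes that fell were FKBP8, a mitochondrial immunophilin (-3.24 ± 0.45), NPIPA1, of a multicopy gene family (-2.77 ± 0.30), FAXDC2 (-2.74 ± 0.48), the protein disulfide isomerase P4HB (-2.62 ± 0.30), MBTPS2 (-2.48 ± 0.31), AKIRIN1 (-2.43 ± 0.31), FN3KRP (-2.31 ± 0.30), SCCPDH (-2.24 ± 0.38), the GTP-binding protein DRG2 (-2.24 ± 0.31) and PCSK1N, an inhibitor of prohormone convertase (-2.23 ± 0.29). Their limma adjusted p lay between 0.0311 and 0.0438. With overexpression the signals of MBTPS2 (15.05) and AKIRIN1 (22.8) lay below the background median of 35.45, so the sizes of these falls are not exact. Other probe sets did not show the fall for FKBP8 (0.70 and 0.26), FAXDC2 (0.77 and 0.37), P4HB (0.01), SCCPDH (0.17) and DRG2 (0.47).

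Camera passed none of the other 21 lists with overexpression against control (adjusted p from 0.0635 to 0.9997). Among markers of other cell types, leukocyte genes had a median of 0.88 (adjusted p = 0.134), basal epithelial genes 0.68 (0.433), luminal epithelial genes -0.42 (0.132), neuroendocrine genes -0.25 (0.797) and stromal genes 0.26 (0.243). Of growth signalling lists, BMP and TGF-beta genes had a median of -0.01, Wnt genes -0.00, Notch genes -0.00 and mesenchymal and adhesion genes 0.14. Stress lists had -0.26 for the unfolded protein and integrated stress response (0.0635), -0.01 for p53 targets, -0.07 for pro-apoptotic and -0.10 for anti-apoptotic genes, -0.02 for the interferon response, 0.34 for NF-kB targets and 0.04 for immediate early genes. Androgen-repressed genes had 0.08, G1/S genes -0.39 (0.0903), G2/M genes -0.30 (0.0872), cholesterol synthesis -0.24 and the RNA interference machinery -0.07. For p53 targets and the lists of BMP and TGF-beta, Wnt, Notch and RNA interference genes, the mean was above 0 while the median and camera's direction were below.

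The direct comparison of overexpression with siRNA spans the widest range of HOXC6. IGFBP3 fell by 2.71 ± 0.41 on the log2 scale, 6.54-fold (limma adjusted p = 0.0364 over all genes, 0.00119 adjusted over the list alone), and its other probe set had -1.56. MME had -1.77 ± 0.39 and BMP7 3.04 ± 0.88, which passed when adjusted over the list alone (0.00533 and 0.0145), evidence that is not independent, but not over all genes (0.0569 and 0.0940); FGFR2 had 1.16 ± 0.57 (0.0798). BMP7 had 1.93 without siRNA replicate 1, 4.14 without siRNA replicate 2 and 1.52 as the mean over its probe sets, and FGFR2 had 0.30 without overexpression replicate 1 and 2.02 without overexpression replicate 2. The list call of BMP7 ended without siRNA replicate 1 (adjusted p = 0.0930) and without overexpression replicate 1 (0.0696), in a range over left-out arrays of 0.00584 to 0.0930. HOX genes were again higher, 10 of 13 with a median of 0.81 (camera adjusted p = 0.0333; adjusted p = 0.846 with an estimated correlation). The filter favoured higher members in this comparison as well. The HOX call ended without siRNA replicate 1 (0.0874), without overexpression replicate 1 (0.165) and with a filter at the 60th percentile (0.361), within a range over alternatives of 0.0130 to 0.361; the median was 1.39 without siRNA replicate 2 and 1.36 without overexpression replicate 2. HOXB1 (2.56 ± 0.29) and HOXC13 (2.12 ± 0.39) rose over all genes, and 6 members were higher and 1 lower when adjusted over the list alone, the lower one being HOXB13, a prostate lineage factor (-1.38 ± 0.44). IGFBP3 passed again after quantile normalization (adjusted p = 0.0496) and cyclic loess (0.0476), within a range over alternatives of 0.00676 to 0.208. It missed the threshold with a pseudocount of 1 (0.0603), with only the 2 groups in the fit (0.0602) and with array weights (0.0560). It also missed it without any 1 of the 5 arrays other than overexpression replicate 2, where the adjusted p ran from 0.0602 (each control array) to 0.208 (siRNA replicate 1), with 0.130 without siRNA replicate 2 and 0.0958 without overexpression replicate 1.

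Of the other lists, oxidative phosphorylation (46 of 55 lower, median -0.41, adjusted p = 4.26e-05), cytosolic ribosomal proteins (43 of 50, -0.41, 9.45e-05), heat shock genes (12 of 14, -0.56, 0.0112) and the proteasome (21 of 27, -0.28, 0.0283) were lower, each with an adjusted p = 0.846 with an estimated correlation. RPL23A (-1.62 ± 0.29) and RPS3 (-1.58 ± 0.28) fell over all genes and adjusted over the list alone. In limma's test heat shock genes had 0 calls over all genes (5 members at an unadjusted p under 0.05) and, adjusted over the list alone, HSPB1 (-1.40 ± 0.35) and FKBP4 (-1.20 ± 0.31) lower and HSPA4 higher (1.08 ± 0.27). The other probe set of FKBP4 had 0.11, and those of HSPA4 lay between -1.13 and 1.14. NDUFC1 had -1.36 ± 0.28 and PSMD8 -0.90 ± 0.28; limma passed 0 members of their lists over all genes or adjusted over the list alone, with 10 and 5 at an unadjusted p under 0.05. The spike-in signal of the siRNA arrays was 0.746 times the control mean, against 2.78 with overexpression, and all 5 list calls ended after quantile normalization and cyclic loess; proteasome medians there were 0.06 and 0.15, and after cyclic loess the ribosomal median was 0.09, heat shock -0.21, oxidative phosphorylation -0.07 and HOX genes 0.57. Among random lists of like signal, medians stood at the percentile 96.2 for HOX genes, 5.92 for heat shock, 48.1 for oxidative phosphorylation, 82.2 for ribosomal proteins and 86.7 for the proteasome. Again the lists of oxidative phosphorylation, ribosomal proteins and the proteasome were not low for their signal. Without siRNA replicate 1 there were 2 lists past the threshold, and 2 without overexpression replicate 1; in both cases the HOX, heat shock and proteasome calls had ended. Without overexpression replicate 1 the medians were -0.24 for ribosomal proteins and -0.17 for the proteasome, and without overexpression replicate 2 that of oxidative phosphorylation was -0.64. The proteasome call also ended without control replicate 1 and with a filter at the 60th percentile. The other 25 lists did not pass (medians from -0.58 to 0.87, adjusted p from 0.0635 to 0.932); median, mean and camera's direction differed in sign for G2/M, anti-apoptotic, BMP and TGF-beta, Wnt and Notch genes.

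Over all genes limma called 264 between overexpression and siRNA, 180 higher and 84 lower (68.2% higher), with 2187 at an unadjusted p under 0.05. After quantile normalization 44.5% of the calls were higher, after cyclic loess 51.1% and after median centring 29.98%. The arrays did not overlap for 57.5% of genes, against 33.3% by chance. Of the higher calls 94 were shared with overexpression against control, where independent lists would share 3.65, and of the lower calls 44 (0.64); both comparisons use the same overexpression arrays. Besides HOXC6, genes that rose were MAP2K5 (4.78 ± 0.29), GRIN1 (3.81 ± 0.38), the kinesin KIF25 (3.64 ± 0.32), CRMP1, a mediator of semaphorin signalling (3.62 ± 0.32), PLEKHO2 (3.54 ± 0.67), RAB2A (3.54 ± 0.43), SEPT5-GP1BB (3.39 ± 0.47), REEP2 (3.30 ± 0.53), FOLR2 (3.28 ± 0.32), the blood group protein KEL (3.23 ± 0.35) and C1QTNF1 (3.13 ± 0.55). With siRNA the signals of KIF25 (7.35), REEP2 (9.25), CRMP1 (11.7), KEL (12.6), SEPT5-GP1BB (12.85) and FOLR2 (13.25) lay below the median of bacterial probe sets that are not spiked (14.85), so the sizes of these changes are not exact and set no order. For KIF25 the other probe set had 2.80, while those of MAP2K5 (-0.11 to 0.89) and RAB2A (-0.61 to 0.23) stayed lower. Besides IGFBP3, genes that fell were FAXDC2 (-3.06 ± 0.48), NPIPA1 (-2.90 ± 0.30), the homeobox factor PITX1 (-2.66 ± 0.52), the chaperone cofactor SIL1 (-2.62 ± 0.52), AKIRIN1 (-2.61 ± 0.31), FKBP8 (-2.48 ± 0.45), POR (-2.44 ± 0.30), the tubulin cofactor TBCD (-2.44 ± 0.36), DAZAP2 (-2.40 ± 0.31), ESYT1 (-2.39 ± 0.34) and P4HB (-2.36 ± 0.30). Other probe sets did not show the fall for FAXDC2 (0.20 and 0.37), FKBP8 (0.93 and 0.37), TBCD (-0.08 and 0.52) and P4HB (0.03). With overexpression POR (16.45), AKIRIN1 (22.8) and TBCD (30.8) lay below the background median of those arrays (35.45), so their sizes are not exact either. The count was 2 without either control array or overexpression replicate 1, 1 without either siRNA array, and 1355 without overexpression replicate 2. It was 61 at a pseudocount of 1 and 718 at 64, 114 without a filter, 447 after median centring, 2 with only the 2 groups in the fit, 36 with array weights and 591 with an intensity trend.

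Comparing the change after lowering HOXC6 with the change after raising it asks which genes follow its level in both directions. IGFBP3, the channel TRPM4 and the orphan nuclear receptor NR4A1 were among genes with changes of opposite sign at an unadjusted p under 0.05 in both: 9 genes were higher with siRNA and lower with overexpression and 14, HOXC6 included, were the reverse. Another 52 were higher in both and 20 lower in both, so 24.2% had opposite signs. The shared control arrays alone gave 0.04 opposite and 76.8 alike on average in 100 simulations without any effect, and these leave out the broad change with overexpression, so neither count is a number of genes that follow HOXC6. DAZAP2 had 1.56 with siRNA and -0.84 with overexpression, TRPM4 1.11 and -1.11, the translation factor EIF3A 1.00 and -1.20, the ubiquitin ligase RNF41 0.97 and -1.02, the transcription factor SOX4 0.89 and -0.87, and IGFBP3 1.21 and -1.50. In the other sense, NR4A1 had -1.10 and 1.35, PRDM14 -1.17 and 1.11, C1QTNF1 -1.34 and 1.80, the acyltransferase MOGAT2 -1.03 and 1.84 and GPR173 -1.06 and 1.05. Other probe sets of NR4A1 had -0.03 and 0.05 with siRNA, and those of DAZAP2 lay between -0.43 and 0.26, of EIF3A between -0.58 and 0.15 and of SOX4 between -0.56 and 0.16 with overexpression. Moving the same way were SLC43A3 (1.58 and 2.92), DEFB1 (1.41 and 2.71), GBP1 (1.95 and 1.56), GNMT (1.70 and 1.56), ETV2 (1.51 and 1.90) and ACAP1 (1.43 and 3.76) upward, and MBTPS2 (-1.72 and -2.48), PANK3 (-1.66 and -1.56), MEF2A (-1.47 and -1.59), SCML1 (-1.29 and -1.64), SERINC5 (-1.15 and -1.15) and BCL9 (-1.04 and -1.70) downward. Of these genes, none passed with siRNA, and SLC43A3, DEFB1, ACAP1 and MBTPS2 passed with overexpression. The control signals of SLC43A3, GBP1, DEFB1 and ETV2 and the overexpression signals of MBTPS2, MEF2A, BCL9 and RNF41 lay below the background medians of those arrays, so their sizes are not exact.

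Across the 8230 genes, which are not independent replicates, the log2 changes with siRNA and with overexpression correlated with Pearson's r = 0.185 and Spearman's rho = 0.162. Both comparisons share the 2 control arrays, which alone gave r = 0.499 and a covariance of 0.0834 in simulations without any effect, against an observed covariance of 0.0605. That simulated r holds where both changes have a like spread. The observed SD across genes was 0.378 with siRNA and 0.865 with overexpression, so the 2 values of r are not directly comparable. With a different control array for each comparison, r was 0.0855 under one assignment and -0.161 under the other. It was 0.412 without control replicate 2 and 0.0099 without siRNA replicate 2, so single arrays decide it.

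**Figure D4:**
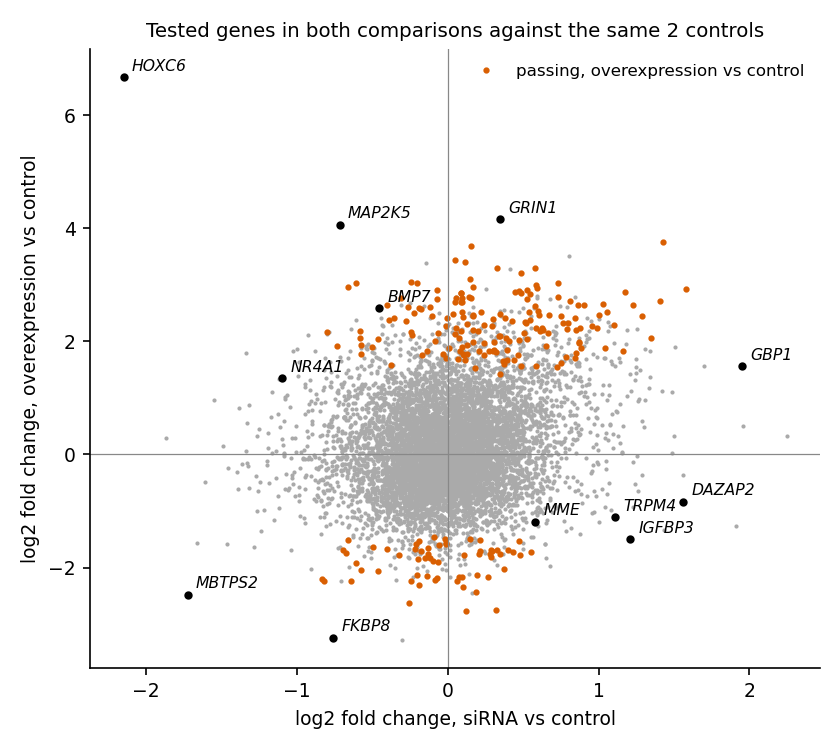
Log2 change with overexpression (vertical axis) against log2 change with siRNA (horizontal axis), both against the same 2 control arrays, 1 point per tested gene; orange marks genes that passed with overexpression and black the genes labelled by name. The cloud has r = 0.185, IGFBP3 lies at 1.21 and -1.50, and HOXC6 at -2.15 and 6.67.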

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

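The tests of explanations in this part were chosen after the results were seen. In probe sets that the comparisons do not use, 5 measures of the overexpression arrays lay above the level in the control arrays. Spike-in probe sets had a mean log2 signal 1.48 above the control mean (1.74 and 1.22 on the 2 arrays, against 0.04 and -0.04 on the controls). Bacterial probe sets that are not spiked lay 0.57 above it (0.81 and 0.32, against -0.02 and 0.02). Ribosomal RNA probe sets lay 1.57 above it (1.14 and 2.00, against -0.81 and 0.81 on the controls and -0.74 and 1.61 with siRNA). The 3' minus 5' log2 difference was 1.14 for ACTB, against 0.37 in the controls, and 0.30 for GAPDH, against -0.33.

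A first pattern is the 167 genes higher with overexpression than in control. Of these, 92 were called again after cyclic loess, which removes the trend of change with signal. Their median log2 change was 2.52 before and 2.20 after. The trend, a median of 0.47 in genes with a mean signal of 50 to 100, was too small to be the whole source of these calls. The genes were picked for large changes on these same arrays, so the outcome was in part fixed in advance. Cyclic loess leaves other differences of the overexpression arrays in place, such as the raised background, and does not argue against them. For the other 75 the median went from 2.04 to 1.65 and the standard error from 0.37 to 0.35; their calls ended because the change shrank (adjusted p from 0.0507 to 0.122), and how far the signal range made them cannot be told apart from a rise in expression. After cyclic loess the other probe sets of 52 of the 76 genes that have any were higher (68.4%, exact 95% interval 56.7% to 78.6%), against 43.1% of uncalled genes of like signal. The interval treats genes as independent, but all rest on the same arrays, so it does not measure the spread between cultures. These shares argue only against noise confined to single probe sets as the source of the direction of the set. A difference between arrays that all probe sets of a gene share stays possible, since uncalled genes were not matched on control signal. The other probe sets had a median log2 change of 0.28, and as deposited 47 of 144 were at least 2-fold higher, so they did not show the size of the rise. An effect of the HOXC6 level stays open, as does a difference in RNA or array handling that coincides with the vector: with siRNA the 166 genes other than HOXC6 had a median change of 0.30 (interquartile range 0.55), but the shared control arrays pull that value upward, and at a median control signal of 28.7 the genes had little room to fall.

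A second pattern is the lower level of androgen-induced and G2/M genes and the higher level of androgen-repressed genes with siRNA. By list median the androgen-induced genes were lower in each siRNA array than in each control array, but the nearest pair differed by -0.0724 where the control arrays differed by 0.34, so a difference between the control arrays cannot be told apart from an effect of the siRNA. For G2/M genes the nearest pair had the siRNA array above the control array (0.0863) and the other 3 pairs had -0.31, -0.40 and -0.70, with control arrays 0.30 apart; the first value is consistent with a difference between the control arrays, and an effect of the siRNA was not excluded. By list median the 6 androgen-repressed genes were higher in each siRNA array than in each control array, by 0.33 to 0.80. The control arrays differed by 0.13 and the siRNA arrays by 0.29. Every gap exceeded the control difference, but the nearest was close to the siRNA difference. By chance 2 arrays lie apart from 2 others in 33.3% of cases. The values thus argue only weakly against the difference between the control arrays as the whole source. An effect of the siRNA and other differences between cultures stay open. If androgen-induced genes followed the HOXC6 level they would be higher with overexpression; after cyclic loess their median there was -0.11 (adjusted p = 0.300, within a range over alternatives of 0.000633 to 0.302), which did not decide it.

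The last pattern is the 63 genes lower with overexpression, several of which have other probe sets that did not fall. Of the 18 that have any, 7 had other probe sets that were lower after cyclic loess (38.9%, exact 95% interval 17.3% to 64.3%), against 57.5% of uncalled genes of like signal. The interval holds the share of uncalled genes, so by direction the other probe sets did not set the called genes apart. Their median log2 change was 0.12, and 0.33 as deposited, where 4 of 36 other probe sets were at least 2-fold lower. The called probe sets of the 63 genes had a median of -1.78. For the genes covered, the other probe sets did not show a fall of the whole transcript, but they cannot exclude one. The interval, which treats genes as independent, is wide. The tested probe set was the brightest of each gene, so the others may show a fall less well. Dim signals also lay higher on the overexpression arrays, where bacterial probe sets that are not spiked were 0.57 above the control mean. A loss of signal in single probe sets was not shown either. No biological explanation was tested for this pattern.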

How the results depend on the processing

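Cyclic loess, array weights and the block with exchanged numbers were chosen after the data were seen; the other alternatives were fixed before. With siRNA, 0 genes passed in limma under all 19 alternatives and the 2-fold minimum (147 to 412 at an unadjusted p under 0.05). HOXC6 kept its direction and its side of the threshold in each comparison, except without control replicate 1, where overexpression against control had an adjusted p of 0.0571; leaving out arrays gave log2 changes from 6.23 to 7.11.

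The counts of overexpression against control (230) and against siRNA (264) moved far more. They were 6 and 61 with a pseudocount of 1, 626 and 718 with 64, 43 and 114 without a filter, 152 against control after quantile normalization, 447 against siRNA after median centring, 2 and 2 with a replicate block, 1 and 2 with only the 2 groups in the fit, 481 and 591 with an intensity trend, and 7 and 36 with array weights. Leaving out arrays gave 0 to 1242 and 1 to 1355. Against control the count was 0 without control replicate 1, 1 without control replicate 2, without either siRNA array or without overexpression replicate 1, and 1242 without overexpression replicate 2. Against siRNA it was 2 without either control array or overexpression replicate 1, 1 without either siRNA array, and 1355 without overexpression replicate 2. Fits with fewer arrays or a block have fewer residual degrees of freedom. Array weights keep all 6 arrays and also cut the counts, so fewer degrees of freedom are not the only source. The main fit used 1 spread per gene for all groups. Between the arrays of a group, the root mean square SD was 0.592 with overexpression, 0.410 in the controls and 0.390 with siRNA. Beyond this the cause was not tested. Of the 167 higher and 63 lower genes against control, quantile normalization kept 69 and 56, median centring 109 and 63, and cyclic loess 92 and 51.

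Replicate numbers pair the arrays only by a shared number. The replicate differences correlated across genes by 0.332 between control and siRNA but by -0.145 between control and overexpression, and a block with the overexpression numbers exchanged gave 370 and 462 genes. With the replicate block IGFBP3 missed the threshold against siRNA (adjusted p = 0.0539, within a range over alternatives of 0.00676 to 0.208).

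Lists past the camera threshold (7 with siRNA, 9 with overexpression against control, 5 against siRNA) were 2, 0 and 0 after quantile normalization, 3, 0 and 0 after cyclic loess, and 4 with siRNA after median centring. With an estimated correlation and with fry they were 0, 0 and 0, at a lowest adjusted p of 0.846 and 0.355. Against siRNA they were 9 without a filter and 3 at the 60th percentile. Leaving out arrays gave 2 to 6, 3 to 12 and 2 to 6: with siRNA 2 without control replicate 1, 2 without siRNA replicate 2 and 4 without overexpression replicate 1; against control 4 without control replicate 1 and 3 without overexpression replicate 1; against siRNA 2 without siRNA replicate 1 and 2 without overexpression replicate 1. The camera direction of G1/S genes with siRNA turned without control replicate 1 (median -0.0428, in a range of -0.53 to -0.0428 over left-out arrays). Ribosomal medians turned to 0.037 (quantile) and 0.20 (cyclic loess) against control and 0.0929 (cyclic loess) against siRNA, and the proteasome median against siRNA to 0.0631 (quantile) and 0.15 (cyclic loess). The cause was not tested.

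Of 1553 values of named genes with overexpression against control, 1164 kept direction and side, 306 were weaker and 83 stronger; against siRNA, of 866, these were 577, 238 and 51. With siRNA 1174 of 1179 were kept and 5 turned: BMP7 to 0.29 with the mean over probe sets, and to 0.64 without control replicate 2 and 0.65 without siRNA replicate 1 (range over left-out arrays -1.56 to 0.65), and FGFR2 to 0.21 and 0.02 (range -0.47 to 0.21). The correlation of siRNA and overexpression changes was -0.161 with control replicate 2 for siRNA and replicate 1 for overexpression, and 0.0099 (without siRNA replicate 2) to 0.412 (without control replicate 2) over left-out arrays. The cause was not tested. Signal over background limits dim genes. On the overexpression arrays the highest probe set for a transcript that is not spiked read 97.6. Of the 167 higher genes, 164 lay above it. The filter favoured this outcome in advance, since it asked for a mean of 51.5 over the 6 arrays. These genes had a median control signal of 28.7 (upper quartile 44.9). Most of them could pass the filter only through higher signals on the other arrays. The count is therefore no evidence of signal above background.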

Other observations

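The genes of this part were chosen after their values were seen, from members of the fixed lists that passed limma's test singly; no hypothesis beyond those above was tested. With overexpression, FOSL1, an AP-1 subunit of the immediate early list, rose by 1.78 ± 0.33 on the log2 scale against control (limma adjusted p = 0.0439 over all genes, n = 2 per group) and by 2.36 ± 0.33 against siRNA (0.0356). The orphan nuclear receptor NR4A1 rose by 2.45 ± 0.34 against siRNA (0.0356). Its other probe sets stayed close to control with siRNA, as given above, so the siRNA part of that difference rests on 1 probe set. For the other genes of this part, values of other probe sets are not given. SMAD6, an inhibitor of BMP signalling, rose by 1.88 ± 0.35 against control (0.0442), the matrix proteoglycan DCN (decorin) by 2.27 ± 0.42 (0.0450) and the chromatin assembly subunit CHAF1B by 2.47 ± 0.43 (0.0438). After cyclic loess these changes against control were 1.38 for FOSL1, 1.54 for SMAD6, 1.78 for DCN and 2.33 for CHAF1B. The control signal of DCN (14.9) lay near 13.15, the median there of bacterial probe sets that are not spiked, so the size of its rise is not exact. CHAF1B went against its list, where 21 of 28 G1/S genes lay below control. The stress-responsive transcription factor CEBPB fell against siRNA (-1.71 ± 0.31, 0.0445). Their lists as groups did not pass camera, and without any 1 array other than overexpression replicate 2 no more than 2 genes passed in either comparison. HPGD, in the androgen-induced list, was higher with overexpression than with siRNA (0.0319), where its mean signal of 6.20 lay below 14.85, the median of bacterial probe sets that are not spiked, so no size is given.

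Adjusted over the list alone, the adhesion genes ITGB3 (1.74 ± 0.35), ITGA5 (1.84 ± 0.48) and N-cadherin (CDH2, 1.32 ± 0.30) were higher with overexpression than in control, as were the collagens COL1A2 (1.54 ± 0.40) and COL3A1 (1.26 ± 0.32), the initiator caspase CASP8 (1.94 ± 0.41) and AGO4 (2.06 ± 0.43). The neuronal enolase ENO2 (-1.73 ± 0.38), the chemokine CCL2 (-1.61 ± 0.35) and the endoplasmic reticulum chaperone HSP90B1 (-3.28 ± 0.65) were lower, while DDIT3, a transcription factor of the same stress list as HSP90B1, was higher (1.51 ± 0.32). With overexpression ENO2 (15.55) and CCL2 (20.15) lay below the median of bacterial probe sets that are not spiked (35.45), so the sizes of their falls are not exact. Over all genes limma's adjusted p of these 11 missed the threshold, reaching 0.0795. In this comparison 2091 of 8230 genes had an unadjusted p under 0.05, and the adjustment within a list does not cover the number of lists, so such calls arise readily. Their lists as groups did not pass camera. Of mesenchymal and adhesion genes 7 of 13 lay above control (median 0.14, camera adjusted p = 0.433), and stromal genes had a median of 0.26 (0.243). The higher ones had mean control signals from 15.4 for AGO4 to 80.9 for ITGA5, apart from DDIT3 at 163.6. Of 27 bacterial probe sets that are not spiked, the largest rise against control was 1.57, and the changes of COL1A2, COL3A1, CDH2 and DDIT3 were no larger than that.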
